A study of Mus musculus with 18 samples.

How the data were processed

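Whole retinas of tamoxifen-treated mice with floxed Map3k12 (DLK), with or without a CAG-driven Cre-ERT transgene, were profiled 3 days after optic nerve crush on 2-colour Agilent mouse gene expression arrays. Per the labels, retinal RNA was labelled with Cy5 and a universal mouse reference RNA with Cy3. The deposited scanner files, 1 for each of 18 arrays, hold the median intensity of each spot and of its local background in both dyes, in scanner intensity units with no normalization. The same deposited files hold processed signals, intensity values from which Agilent Feature Extraction 10.7.3.1 had removed background and spatial trend and to which it had applied a dye normalization, at a pixel size of 5 micron. They also hold a deposited log10 ratio of processed Cy5 over Cy3, which differed from the ratio recomputed from the processed signals by at most 0.084 on non-control spots. The authors' table of 1 value per probe and array names limma as a tool, and its version, background correction and normalization are not given in the sources used here. Its scale was not stated and was taken to be log2 of Cy5 over Cy3, because the deposited values correlated at r of 0.999 to 1 across probes with the log2 ratios computed here, with slopes of 1 to 1.02 and column medians of 0.015 to 0.024. After each probe's mean over arrays was removed, r across probes was 0.95 to 1.

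Ratios were computed in R 4.3.3 with limma 3.58.1, and the files were read with version 1.17.8 of the data.table package. Spot and local background intensities were combined by limma's normexp correction with an offset of 50, followed by loess normalization within each array. The plan named the mean spot intensity, which the files do not hold, so the median was used. The offset pulls ratios of dim spots toward 0, so changes of dim genes are underestimated. Each array held 43020 non-control spots of 39429 probes, and spots of the same probe were averaged. Of these probes 26581 could be paired with 1 of 20144 symbols through their RefSeq accession, and 12848 had no symbol and were tested as single probes. Each gene was represented by its probe with the highest mean intensity. Probes were kept where Cy5 was well above background on at least 3 arrays, which left 25131 genes, 16793 of them with a symbol, and 49 missing values. No genomic positions are given, because the array header and the reference table name different genome builds.

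The 17 arrays with agreed labels were fitted in limma with a mean for each of 4 groups, giving 13 residual and 4.49 prior degrees of freedom. The 5 contrasts were the crush response in Cre-negative and in Cre-positive retinas, the difference between them, and the Cre effect in uncrushed and in crushed retinas. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, computed over all genes within a contrast, and all tests were two-sided. The median log2 change over all genes was 0.0015, 0.00046, 0.0026, 0.0073 and 0.0088 in the order of those contrasts. Map3k12 and Esr1 were also compared between genotypes by exact permutation of the array labels. The array with disagreeing labels was left out, and its values did not decide its group. Adding it to either possible group was among the alternatives.

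In all 23 gene lists were fixed: integrated stress response, axon injury and regeneration-associated genes, AP-1 and JNK pathway, immediate early genes, apoptosis, p53 targets, reactive gliosis, interferon response and complement, cholesterol synthesis, and markers of ganglion cells, rods, cones, bipolar, amacrine and horizontal cells, Müller glia, astrocytes and oligodendrocytes, microglia and macrophages, vascular cells, red blood cells, lens, pigment epithelium, and cornea, iris and ciliary body. Of their 404 entries 402 were on the array, and 3 carried an older symbol that was updated. Some genes are in several lists. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 23 lists within a contrast. Of the 115 tests camera called 49, of which 26 held with an estimated correlation, and fry called 35. Camera compares a list with the other genes, while fry asks whether its members move, on balance, one way. Where a list had no call, the sign of its median and the direction of its test could differ, as for rod markers after crush in Cre-negative retinas.

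Named genes were, for each contrast, the 10 largest rises and the 10 largest falls among called genes with a symbol and with Cy5 well above background on every array of the brighter group. To these were added up to 4 members of each list with the smallest adjusted p, and 20 genes chosen for their part in axon injury, DLK signalling, ganglion cells and glia. The groups, contrasts, lists, naming rule and most alternatives were set before the data were examined. The alternatives were processed signals, no background subtraction, Aquantile scaling, the Cy5 channel alone, the authors' value table, other filters on dim probes, the mean over probes, slide as a fixed or random term, only the groups compared, other variance models, either placement of the array with disagreeing labels, and leaving out each array in turn. Slide within Cre genotype, the position pair on the slide (1 and 2, or 3 and 4), sex read from Xist, and leaving out the cornea-rich and the lens-rich array were added after the data had been seen. Each count of called genes was also set against other splits of the same arrays.

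The model was tested on simulated data, in which 100 of 25082 genes were given a log2 change of 0.5 and another 100 a change of 1 in Cre-negative retinas alone. The Cre-negative crush contrast recovered 77% of the former and 100% of the latter, with 8.76% false calls, and the difference recovered 58% and 96%, with 4.94% false calls. With the same changes in both genotypes, the Cre-negative contrast recovered 83% and 98%, with 2.69% false calls, and the difference called 0 genes.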

Results

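Gene expression was measured in whole mouse retinas 3 days after crush of the optic nerve, the tract of axons that carries the output of the retinal ganglion cells to the brain. The mice carried floxed alleles of Map3k12, which encodes dual leucine zipper kinase (DLK), a kinase upstream of JNK signalling. Cre-positive mice also carried a tamoxifen-inducible Cre recombinase fused to part of the estrogen receptor, expressed from the widely active CAG promoter, and all mice were dosed with tamoxifen at 10 to 12 weeks of age. Each of 18 arrays, printed on 5 slides, held Cy5-labelled retinal cRNA against a Cy3-labelled reference pool of mouse RNA, and values are log2 of Cy5 over Cy3. The labels place 4 arrays in the Cre-negative uncrushed group, 3 in the Cre-negative crushed group, 5 in the Cre-positive uncrushed group and 5 in the Cre-positive crushed group. The remaining array, from a Cre-negative mouse, is uncrushed by its title and treatment but crushed by its description, and it was kept out of every comparison.

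On each array 68.8% to 76.9% of probes had Cy5 well above background. The median Cy5 signal was 240 to 297 intensity units over a local background of 72.5 to 84, and no array had a saturated spot (0 in all). Pearson's r across genes between arrays of the same group was 0.992 to 0.996 in Cre-negative uncrushed, 0.99 to 0.995 in Cre-negative crushed, 0.982 to 0.994 in Cre-positive uncrushed and 0.987 to 0.995 in Cre-positive crushed retinas. Genes are not independent replicates, so these describe the arrays only. The median SD of a gene between arrays was 0.089 and 0.086 in the uncrushed and crushed Cre-negative groups and 0.11 in both Cre-positive groups. The number of arrays limits the precision. The labels do not say that the samples come from separate animals, so each p-value measures the spread between these samples.

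The first comparison asked whether the retinas carried the genotype their labels state. The single Map3k12 probe was lower in Cre-positive retinas, at 2.01 ± 0.18 (SD, n = 10) against 2.46 ± 0.15 (SD, n = 7) in Cre-negative ones. The limma estimate of the mean Cre effect over crushed and uncrushed retinas was -0.45 on the log2 scale (SE 0.08, adjusted p = 0.0075). A two-sided exact permutation test over all arrays, added to the limma test, gave a difference of -0.44, which leaves 73.5% of the Cre-negative level (p = 0.00026 over 19448 splits). Here and for Esr1 below, crushed and uncrushed retinas count as separate units, though some may be eyes of the same animal. The difference was -0.43 among uncrushed retinas (exact permutation p = 0.0079) and -0.47 among crushed ones (exact permutation p = 0.054). Arrays of the genotypes overlapped, with Cre-positive values of 1.77 to 2.34 and Cre-negative values of 2.21 to 2.61. Whether the probe lies in the floxed exon is not given, so 73.5% does not measure how much functional transcript remained. Map3k13, which encodes the related kinase LZK, differed by 0.02 in uncrushed retinas (limma adjusted p = 0.99) and by 0.14 in crushed retinas (limma adjusted p = 0.42).

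One Esr1 probe, for the estrogen receptor whose ligand-binding part is fused to this Cre, separated the genotypes completely. It read 2.71 ± 0.49 (SD, n = 10) in Cre-positive and -0.67 ± 0.12 (SD, n = 7) in Cre-negative retinas, a limma difference of 3.38 (SE 0.11, adjusted p = 6.1e-12). The probe was not well above background in Cre-negative retinas, so Cre-positive Cy5 signal was at least 9.75-fold higher in uncrushed and at least 14.6-fold higher in crushed retinas. Another Esr1 probe differed by -0.07 (two-sided exact permutation p = 0.2), and a further one, near background, by 0.08 (exact permutation p = 0.097).

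**Figure D1:**
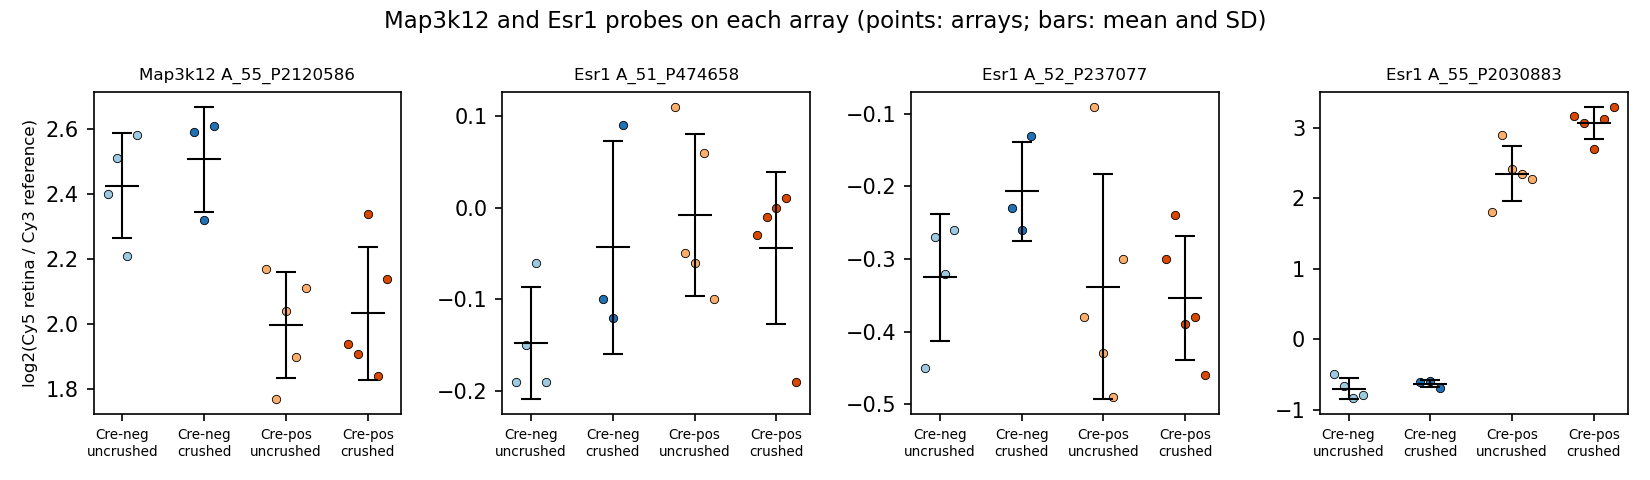
Log2 Cy5 over Cy3 (vertical axis) of the Map3k12 probe and of 3 Esr1 probes in each of the 4 groups (horizontal axis), with 1 point per array and the group mean with its SD. Map3k12 is 0.44 lower on average in Cre-positive retinas with overlapping arrays, and 1 Esr1 probe lies between 1.8 and 3.3 in every Cre-positive array and between -0.84 and -0.5 in every Cre-negative array.

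The crush response with DLK present was read from Cre-negative retinas, 3 crushed against 4 uncrushed. The largest rises were in Ecel1 and Sox11. Ecel1, a membrane peptidase of injured neurons, rose 11.1-fold, from 1.05 ± 0.10 (SD, n = 4) to 4.52 ± 0.03 (SD, n = 3), a log2 change of 3.47 (SE 0.16, limma adjusted p = 2.1e-10). Sox11, a transcription factor of developing and injured neurons, rose 7.61-fold (log2 2.93, SE 0.12, limma adjusted p = 3.3e-11). The largest falls were in the sodium channel subunit Scn4b (log2 -2.03, SE 0.10, limma adjusted p = 4.6e-10) and the ganglion cell transcription factor Pou4f2, which went from 4.43 ± 0.39 (SD, n = 4) to 2.65 ± 0.06 (SD, n = 3), a log2 change of -1.77 (SE 0.15, limma adjusted p = 4.3e-07). In all, 548 of 25131 genes passed an adjusted p of 0.05 in limma, 342 higher and 206 lower, of which 45 rose and 18 fell at least 2-fold.

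After Ecel1 and Sox11 the largest rises were in Chac1 (log2 2.51), a glutathione-degrading enzyme induced by ATF4, in Sprr1a (2.38), a small proline-rich protein of regenerating neurons, and in the chemokine Cxcl10 (2.34). Colec10, a collectin, rose by 2.21 on the fitted scale and was at least 4.81-fold higher in Cy5 signal, as it was not well above background before crush. Hrk, a BH3-only activator of apoptosis, rose by 2.13, the transcription factor Cebpd by 2.10, Gm13889 by 2.04 and the stress-induced transcription factor Atf3 by 1.99. Their limma adjusted p ranged from 3.3e-11 for Colec10 to 0.0027 for Cebpd. The largest falls after Scn4b and Pou4f2 were in the ganglion cell transcription factor Isl2 (log2 -1.69), the RNA-binding protein Rbpms2 (-1.69), Ctxn3 (-1.41), the Iroquois transcription factors Irx2 (-1.40) and Irx4 (-1.27), the nicotinic receptor subunit Chrna6 (-1.38), the calcium channel regulator Fkbp1b (-1.34) and the tubulin-binding protein Tppp3 (-1.26). A second probe of Irx2 gave -0.17 and one of Fkbp1b gave -0.62.

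Of the lists fixed in advance, the integrated stress response had the highest share of changed genes. It rose in 18 of 25 measured members and fell in 0 (20 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.56 and a camera adjusted p of 1.4e-37. Its members included Atf5 (1.32, limma adjusted p = 2e-07), Gdf15 (1.18), Asns (0.95) and Ddit3, the CHOP transcription factor (0.78, limma adjusted p = 2.6e-05). Axon injury and regeneration-associated genes rose in 14 of 28 and fell in 1 (18 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 2.8e-24), led by Ecel1, Sox11, Sprr1a, Atf3 and the TWEAK receptor Tnfrsf12a (1.72). Gap43, a growth cone protein of the same list, gave 0.35 (limma adjusted p = 0.1), and the AP-1 subunit Jun gave 0.77 (limma adjusted p = 0.086). The AP-1 and JNK list rose in 7 of 28 (8 higher and 1 lower adjusted over the list alone; median 0.16, camera adjusted p = 1e-05), with Fosl2 at 0.83 and Maff at 0.69. Immediate early genes rose in 3 of 13, Arc (0.54), Fosb (0.39) and Junb (0.43) (4 adjusted over the list alone; median 0.37, camera adjusted p = 2.8e-06).

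Apoptosis genes rose in 7 of 23 (10 adjusted over the list alone; median 0.17, camera adjusted p = 1.1e-08), including Hrk and Bbc3, which encodes PUMA (0.75, limma adjusted p = 5e-05). The list of p53 targets rose in 3 of 17 (6 adjusted over the list alone; median 0.11, camera adjusted p = 9.1e-07). These included the cell cycle inhibitor Cdkn1a at 0.99, for which another probe gave 0.15, and the death receptor Fas at 0.69 (limma adjusted p = 0.025). Reactive gliosis genes rose in 11 of 21 (14 adjusted over the list alone; median 0.51, camera adjusted p = 2.7e-20), with the peptide Edn2 at 1.87 (limma adjusted p = 8.6e-06), the oncostatin M receptor Osmr at 1.22, Stat3 at 0.98 and Cd44 at 0.60. The intermediate filament gene Gfap rose by 0.77 (SE 0.16, limma adjusted p = 0.015), and its 3 probes ranged from 0.16 to 1.19.

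The interferon and complement list rose in 4 of 26, C4b (1.37), Gbp2 (0.98), Gbp3 (0.95, call lost in 19 of 37 alternatives) and Psmb8 (0.70), and in 20 adjusted over the list alone (median 0.54, camera adjusted p = 1.5e-15). That call was lost at an adjusted p = 0.062 with an estimated correlation. Microglia and macrophage markers rose in 4 of 20, Aif1 (0.84), C1qc (0.64), Ctss (0.57) and Tmem119 (0.52), and in 11 adjusted over the list alone (median 0.29, camera adjusted p = 1.9e-09). That call too was lost, at an adjusted p = 0.062 with an estimated correlation. Cholesterol synthesis genes fell in 2 of 20, among them Fdps (-0.33), and in 6 adjusted over the list alone (median -0.13, camera adjusted p = 6.6e-05), with an adjusted p = 0.051 with an estimated correlation. Fry called these lists, with fry adjusted p = 0.0083 for interferon and complement, 0.0064 for microglia and macrophages and 0.0041 for cholesterol synthesis. The other camera calls after crush in Cre-negative retinas held with an estimated correlation.

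Ganglion cell markers fell in 12 of 24 and rose in 0 (0 higher and 17 lower adjusted over the list alone; median -0.36, camera adjusted p = 1.8e-28). Besides Pou4f2, Isl2, Rbpms2 and Chrna6, these included Pou4f1 (-1.04, limma adjusted p = 1.1e-05), the neurofilaments Nefh (-0.76) and Nefl (-0.60), the surface protein Thy1 (-0.44) and Rbpms (-0.62, lowest of 3 probes, the highest at -0.24). With the scanner software's processed signals in place of the spot medians, Nefl gave 0.08. Its mean Cy5 signal fell from 19800 to 8320 with crush, while its dim Cy3 reference signal went from 104 to 69.8. The ratio therefore understates the fall in Cy5. Sncg gave -0.20 (limma adjusted p = 0.062). For the other retinal cell types camera made no call. Rod markers had a median of 0.02 and 0 of 17 past the test (camera adjusted p = 0.98), cone markers 0.01 and 0 of 11 (1 higher adjusted over the list alone; 0.98), bipolar markers -0.09 and 0 of 15 (0.15), and horizontal markers -0.04 and 0 of 6 (2 lower adjusted over the list alone; 0.15). Amacrine markers had a median of -0.02, with the neuropeptide gene Tac1 higher by 0.47 as the 1 of 15 past the test (0.98). Müller glia markers had a median of 0.04 and 0 of 15 past the test (3 higher and 2 lower adjusted over the list alone; 0.32), vascular markers 0.01 and 0 of 12 (0.98), astrocyte and oligodendrocyte markers -0.03 and 0 of 10 (1 higher adjusted over the list alone; 0.85), and red blood cell genes 0.01 and 0 of 4 (0.98). The mixed test of fry, which counts changes in either direction, passed for amacrine (adjusted p = 0.0018), Müller glia (0.00011) and cone markers (0.016). Among tissues next to the retina, pigment epithelium markers had a median of -0.24 and 0 of 12 past the test (camera adjusted p = 0.27), lens crystallins -0.02 and 0 of 16 (0.85), and cornea, iris and ciliary body markers 0.02 and 0 of 9 (0.77).

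Within the 3 slides that held 1 crushed and 1 uncrushed Cre-negative retina each, Sox11 changed by 2.96, 2.96 and 2.86, Ddit3 by 0.93, 0.68 and 0.82, and Pou4f2 by -2.34, -1.61 and -1.34. The ganglion cell list median was -0.40, -0.44 and -0.44 on those slides, the stress list median 0.59, 0.58 and 0.53, and the gliosis list median 0.60, 0.59 and 0.24. In both genotypes crushed retinas sat at the even and uncrushed ones at the odd positions of a slide, so crush and position parity were not separable within a genotype. With the array of disagreeing labels placed in the uncrushed group, as its title states, 72 genes passed in limma in place of 548, in the crushed group, as its description states, 742 did, and with limma's array weights 1198 did. Ecel1 was 4.36 on that array, against 4.49 to 4.55 in Cre-negative crushed and 0.93 to 1.15 in Cre-negative uncrushed retinas.

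**Figure D2:**
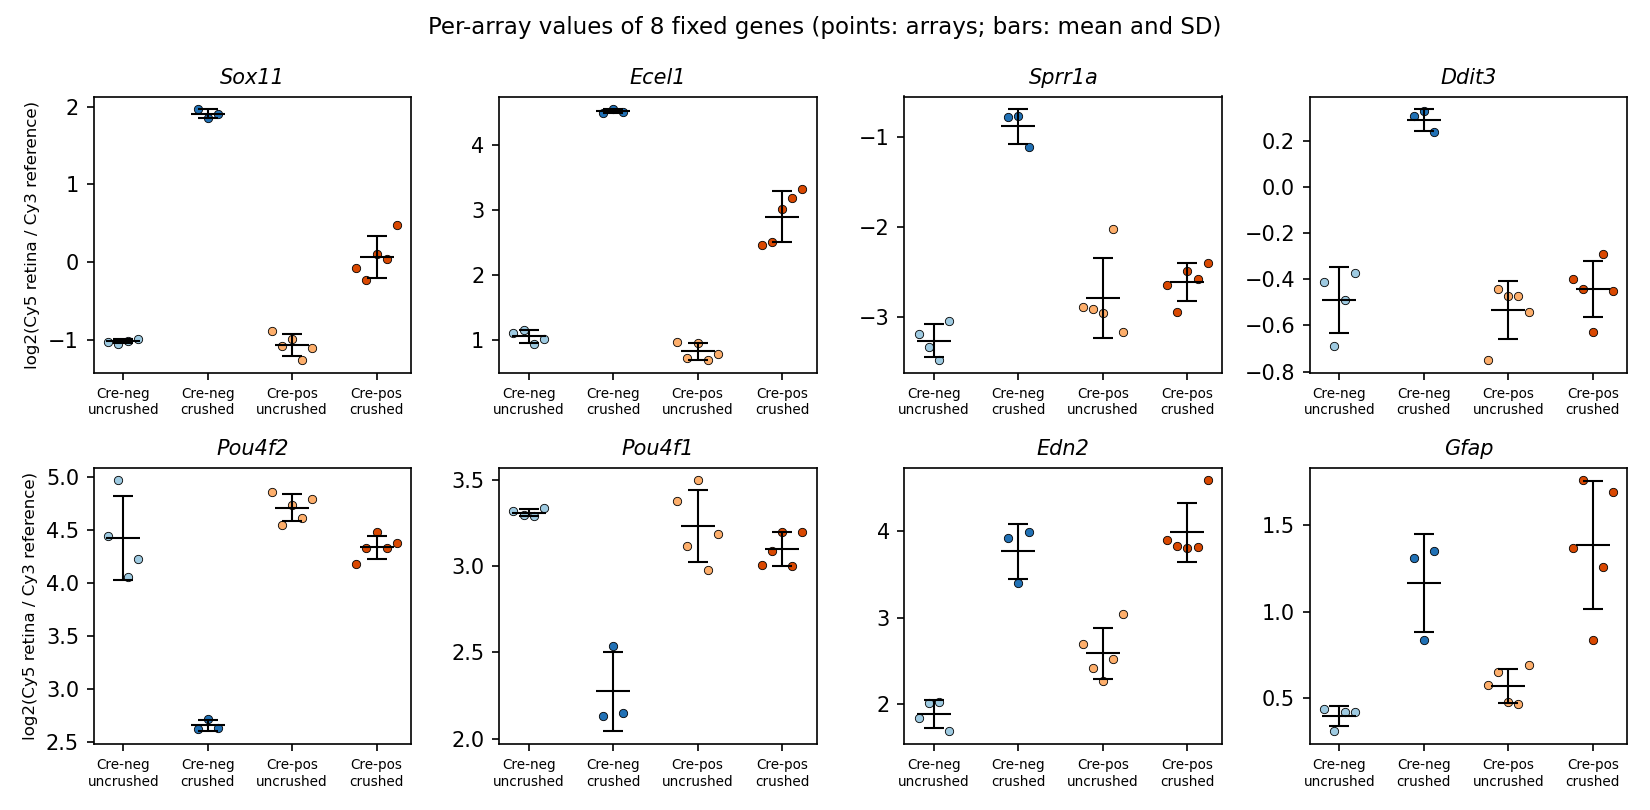
Log2 Cy5 over Cy3 (vertical axis) of Sox11, Ecel1, Sprr1a, Ddit3, Pou4f2, Pou4f1, Edn2 and Gfap in the 4 groups (horizontal axis), with 1 point per array and the group mean with its SD. Sox11, Ecel1 and Ddit3 are highest in the 3 Cre-negative crushed retinas and Pou4f2 and Pou4f1 lowest there, while Edn2 and Gfap lie higher in crushed retinas of both genotypes.

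The crush response with Cre, the means of deleting DLK here, was read from Cre-positive retinas, 5 crushed against 5 uncrushed. Among inflammatory and glial genes, Cxcl10 rose 5.35-fold (log2 2.42, SE 0.29, limma adjusted p = 3e-04), the largest rise called, Cebpd by 2.05, the NF-kappa-B cofactor Bcl3 by 1.55, Edn2 by 1.39, complement C4b by 1.36 and the chemokine Ccl12 by 1.30. Of the neuronal injury genes, Ecel1 had the next largest rise after Cxcl10, of 2.08 (SE 0.13, limma adjusted p = 2.7e-07), while Sox11 rose by 1.13 (SE 0.10, limma adjusted p = 1.4e-05) and Atf3 by 0.90 (SE 0.09, limma adjusted p = 4.1e-05). Falls were small, the largest being Scn4b (-0.64, limma adjusted p = 0.00078), Fkbp1b (-0.58) and Tppp3 (-0.51). In limma 195 genes passed, 173 higher and 22 lower, of which 13 rose and 0 fell at least 2-fold, and 2400 had an unadjusted p under 0.05. With the processed Cy5 signal alone, 77.4% of called genes were higher, against 88.7% here.

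The remaining large rises were in Crh, which encodes corticotropin-releasing hormone (1.21, limma adjusted p = 0.00014), and in Gm833 (1.18, with another probe at 0.05). The other named falls were in the glutamine synthetase gene Glul (-0.50), Rasgrp2 (-0.46), the lipid carrier Fabp5 (-0.41), Spc25 (-0.39), Nefl (-0.36), Dleu7 (-0.36, call lost in 19 of 37 alternatives) and the transferrin receptor Tfrc (-0.36, lost in 22, with another probe at 0.07), with limma adjusted p from 0.0022 for Nefl and Rasgrp2 to 0.047 for Glul. Several genes that passed in Cre-negative retinas did not pass in limma. Sprr1a gave 0.18 (adjusted p = 0.77, and 0.37 with adjusted p = 0.24 without the cornea-rich uncrushed replicate 4), Ddit3 0.09 (0.73), Pou4f2 -0.37 (0.25), Pou4f1 -0.13 (0.68), Nefh -0.28 (0.067), and Rbpms -0.28 (0.11). Jun gave 0.35 (limma adjusted p = 0.57) and Gap43 gave 0.03 (limma adjusted p = 0.93).

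Reactive gliosis genes rose in 12 of 21 (18 adjusted over the list alone; median 0.47, camera adjusted p = 1.5e-27), including Gfap (0.81, limma adjusted p = 0.0059, 3 probes from 0.38 to 1.13), Osmr (0.83) and Vim (0.68). The mean gliosis score was 0.84 in crushed replicate 5, the array highest in the lens gene Cryaa, and 0.18 to 0.30 in the other crushed arrays. Microglia and macrophage markers rose in 12 of 20, and in 12 adjusted over the list alone (median 0.46, camera adjusted p = 2.6e-21), among them Aif1 (0.89), the protease Ctss (0.88) and the complement genes C1qc (0.87) and C1qb (0.57). The interferon and complement list rose in 9 of 26 (22 adjusted over the list alone; median 0.50, camera adjusted p = 9.2e-26), with Gbp2 at 0.86, Serping1 at 0.64 and H2-K1 at 0.56. Axon injury genes rose in 5 of 28 (11 higher and 1 lower adjusted over the list alone; median 0.19, camera adjusted p = 2.4e-10), Stmn4 among them at 0.47. The AP-1 and JNK list rose in 3 of 28, Atf3, Maff (0.37, call lost in 13 of 37 alternatives) and Jund (0.51, lost in 26), and in 4 adjusted over the list alone (median 0.06, camera adjusted p = 0.00016). The integrated stress response list rose in 1 of 25, Nupr1 (0.92), and in 8 adjusted over the list alone (median 0.11, camera adjusted p = 6.5e-09). Ganglion cell markers fell in 3 of 24, Nefl, Nefm (-0.35, lost in 11 of 37 alternatives) and Rbpms2 (-0.27) (1 higher and 15 lower adjusted over the list alone; median -0.17, camera adjusted p = 2.8e-10). Cholesterol synthesis genes fell in 1 of 20, Idi1 (-0.31), and in 7 adjusted over the list alone (median -0.13, camera adjusted p = 2.8e-09). These calls held with an estimated correlation.

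Other calls in Cre-positive retinas did not hold. Apoptosis genes rose in 4 of 23, Hrk (0.66), Bbc3 (0.49), Fas (0.62, call lost in 11 of 37 alternatives) and Tnfrsf1a (0.46, lost in 10) (4 higher and 1 lower adjusted over the list alone; median 0.06, camera adjusted p = 0.003, and adjusted p = 0.078 with an estimated correlation). The list of p53 targets rose in 2 of 17 (3 adjusted over the list alone; median 0.07, camera adjusted p = 0.026, and adjusted p = 0.11 with an estimated correlation). Fry called apoptosis genes (fry adjusted p = 0.0098) and p53 targets (0.019), but not the rod, cornea, iris and ciliary body, or lens lists. Rod markers had 0 of 17 past the test and a median of -0.08 (camera adjusted p = 0.0011, and adjusted p = 0.23 with an estimated correlation). Cornea, iris and ciliary body markers had 0 of 9 and a median of -0.49 (camera adjusted p = 0.022, and adjusted p = 0.21 with an estimated correlation), with Cre-positive uncrushed replicate 4 highest in Krt12 at 5.54. Lens crystallins had 0 of 16 and a median of 0.13 (camera adjusted p = 0.014, and adjusted p = 0.51 with an estimated correlation), with Cre-positive crushed replicate 5 highest in Cryaa at 3.18. Without those 2 arrays 120 genes passed in place of 195. Müller glia markers rose in 1 of 15, Clu (0.44), and fell in 2, Glul and Spc25, with those gene calls lost in 23, 22 and 25 of 37 alternative analyses (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.97).

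Within the 4 slides with Cre-positive retinas of both treatments, Sox11 changed by 1.20, 1.36, 1.01 and 0.88, Ecel1 by 2.28, 2.36, 1.74 and 1.72, and Pou4f2 by -0.27, -0.49, -0.36 and -0.46. The ganglion cell list median was -0.13, -0.21, -0.14 and -0.21, the stress list median 0.10, 0.15, 0.12 and 0.10, and the gliosis list median 0.37, 1.11, 0.38 and 0.41. With the array of disagreeing labels placed as titled, 10 genes passed in limma, placed as described, 189 did, and with the 2 Cre-positive groups fitted alone, 52 did. That array, from a Cre-negative mouse, enters this contrast through the spread estimated over all groups.

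**Figure D3:**
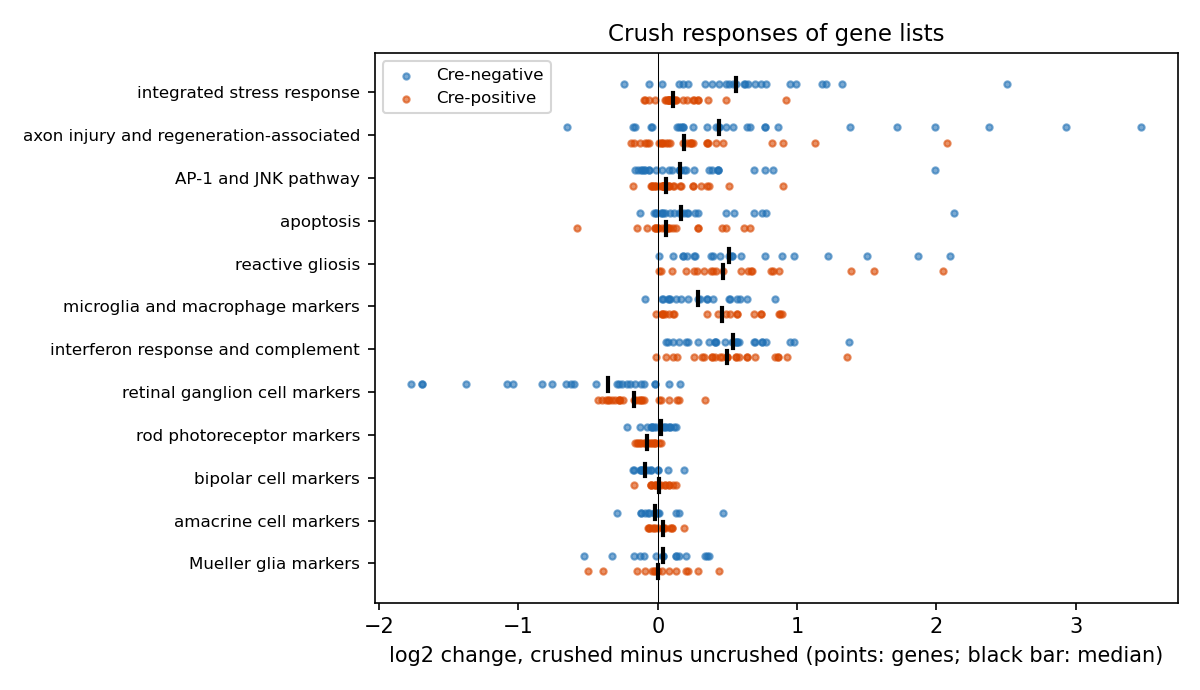
Log2 crush change (horizontal axis) of the members of 12 gene lists (vertical axis), with Cre-negative retinas in blue, Cre-positive retinas in orange and a black bar at each list's median. The stress response medians lie at 0.56 and 0.11 and the ganglion cell medians at -0.36 and -0.17, while those of reactive gliosis lie at 0.51 and 0.47 and those of the interferon and complement list at 0.54 and 0.50.

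The difference between the crush responses, Cre-positive minus Cre-negative, asks which responses differed with the Cre genotype, the means of deleting DLK here. Axon injury and stress genes and the apoptosis genes Hrk and Ddit3 rose less in Cre-positive retinas, and ganglion cell markers fell less. Sprr1a differed by -2.21 (SE 0.26, limma adjusted p = 0.00013, and -2.01 without Cre-positive uncrushed replicate 4), Chac1 by -2.02 (SE 0.18, limma adjusted p = 4.4e-06), Sox11 by -1.80 (SE 0.15, limma adjusted p = 2.8e-06) and Hrk by -1.47 (SE 0.18, limma adjusted p = 0.00023). In the other direction Isl2 differed by 1.43 (SE 0.11, limma adjusted p = 6.1e-07), Rbpms2 by 1.42 (SE 0.08, limma adjusted p = 3.4e-08) and Pou4f2 by 1.40 (SE 0.19, limma adjusted p = 0.00067). In limma 105 of 25131 genes passed, 34 with a positive and 71 with a negative difference, and 9 and 20 of them differed at least 2-fold.

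Other large positive differences were in Ctxn3 (1.52), Scn4b (1.39), Irx2 (1.13, with another probe at 0.03), 1110032F04Rik (1.02), Irx4 (1.00), Chrna6 (0.95) and the potassium channel gene Kcnd2 (0.91), with limma adjusted p from 1e-05 for Scn4b to 0.024 for Chrna6. Other large negative differences were in Colec10 (-1.87 on the fitted scale, as it was not well above background in Cre-negative uncrushed retinas), Gm13889 (-1.76), the cytochrome oxidase subunit Cox6a2 (-1.61), Sprr2g (-1.58), Ecel1 (-1.39) and Tnfrsf12a (-1.37), with limma adjusted p from 3.4e-08 for Colec10 and Gm13889 to 0.0021 for Ecel1. All 105 genes also passed in the Cre-negative crush response, and each was smaller in size in Cre-positive retinas, where the median gene showed 13% of its Cre-negative change and 29 had the opposite sign. The contrasts share arrays, and among simulated unchanged genes 72.3 of 105 were also smaller in Cre-positive retinas, so selection accounts for part of that count. Of the 105, 10 passed in the Cre-positive crush response.

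The integrated stress response list was lower in the difference in 10 of 25 (15 adjusted over the list alone; median -0.42, camera adjusted p = 1.6e-26), including Gdf15 (-1.05), Asns (-0.77), Ddit3 (-0.69, limma adjusted p = 0.0056) and the serine synthesis gene Phgdh (-0.65). Axon injury genes were lower in 8 of 28 and higher in 1 (10 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 9.6e-14), with Atf3 at -1.09. Ganglion cell markers were higher in 5 of 24, among them Pou4f1 (0.91, limma adjusted p = 0.0031), and in 12 adjusted over the list alone (median 0.30, camera adjusted p = 9.8e-17). Apoptosis genes were lower in 2 of 23, Hrk and Ddit3 (3 adjusted over the list alone; median -0.10, camera adjusted p = 0.00026), and p53 targets in 1 of 17, Cdkn1a at -0.88 (2 adjusted over the list alone; median -0.09, camera adjusted p = 0.0031). These calls held with an estimated correlation. Immediate early genes were lower in 1 of 13, Arc at -0.58 (1 adjusted over the list alone; median -0.18, camera adjusted p = 0.0034, and adjusted p = 0.23 with an estimated correlation). The AP-1 and JNK list, lower in 1 of 28 (2 adjusted over the list alone; median -0.10), had a camera adjusted p of 0.0498, and adjusted p = 0.13 with an estimated correlation. Fry called the AP-1 and JNK list (fry adjusted p = 0.025) but not immediate early genes (0.15).

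No difference passed for the glial and immune lists. Reactive gliosis had 0 of 21 past the test and a median of 0.01, with a mean of -0.05 (camera adjusted p = 0.28). Microglia and macrophage markers had 0 of 20 and a median of 0.07 (camera adjusted p = 0.081), and the interferon and complement list 0 of 26 and a median of 0 (camera adjusted p = 0.91). Gfap differed by 0.04 (limma adjusted p = 0.98) and Edn2 by -0.48 (limma adjusted p = 0.64), and a p above the threshold does not show that the responses were equal. Jun (-0.43, limma adjusted p = 0.72), Bbc3 (-0.26, 0.57), Gap43 (-0.32, 0.55), Nefl (0.24, 0.41), Nefh (0.48, 0.062), Thy1 (0.29, 0.17) and Rbpms (0.34, 0.38) did not pass either. The series has no Cre-positive mice without floxed alleles, so Cre activity is not separable from loss of DLK. With the array of disagreeing labels placed as titled 0 genes passed in limma (1972 at an unadjusted p under 0.05) and placed as described 120 did, array weights gave 159, and processed signals gave 68, of which 20.6% had a positive difference against 32.4% here. Among genes called in the difference, that array had Sox11 at 1.81 (Cre-negative crushed 1.85 to 1.97, uncrushed -1.05 to -0.99). Its Pou4f2 was 2.33 (Cre-negative crushed 2.62 to 2.72, uncrushed 4.06 to 4.97).

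Over the 548 genes called in Cre-negative retinas, the slope of the Cre-positive on the Cre-negative change was 0.389 (jackknife SE 0.068). It was 0.448 over genes that rose and 0.231 over genes that fell, and 459 of the 548 had the same sign in both genotypes. Genes chosen in one genotype have overestimated changes there. In the reverse direction, over the 195 genes called in Cre-positive retinas, the slope of the Cre-negative on the Cre-positive change was 1.05 (jackknife SE 0.26). The crush responses shared 98 called genes of the same direction, where independent lists would share 2.53 (two-sided Fisher exact p = 8.9e-111). The genotypes have no array in common, but both contrasts use the same spread estimate for a gene. Genes are not independent replicates either, so that p does not measure a spread between samples. With the array of disagreeing labels placed as titled the crush responses shared 1 gene and the reverse slope was 0.613. Without Cre-negative crushed replicate 1 or 3 they shared 64. Among the shared genes were Ecel1, Sox11, Atf3, Hrk, Bbc3, Edn2, Gfap, C4b and Nefl.

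**Figure D4:**
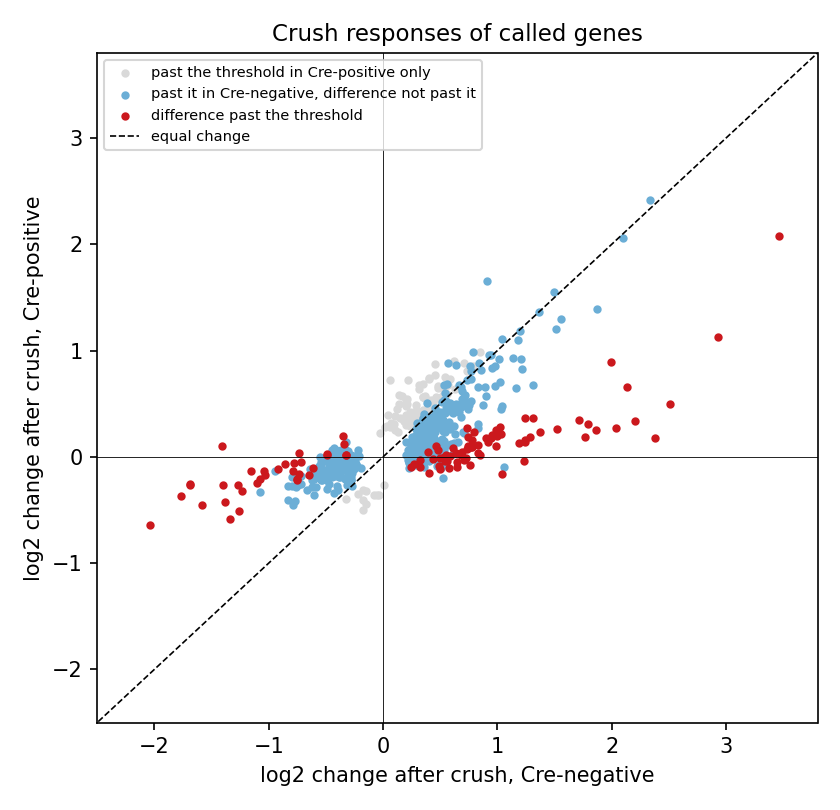
Log2 crush change in Cre-negative retinas (horizontal axis) against that in Cre-positive retinas (vertical axis) for genes called in either, with genes past the test of the difference in red and a dashed line at equal change. The red genes lie between the line and the horizontal axis or just across that axis, and Sox11 is at 2.93 and 1.13 while Cxcl10 is at 2.34 and 2.42.

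The effect of Cre without injury was read from 5 Cre-positive and 4 Cre-negative uncrushed retinas. Besides Esr1 (log2 3.05, SE 0.15, limma adjusted p = 6e-09), 2 genes passed: Lmod3, which encodes the actin-binding protein leiomodin 3 (0.37, SE 0.06, limma adjusted p = 0.039, lost in 25 of the alternatives run), and a probe without a symbol (0.69). All 3 were higher in Cre-positive retinas, and 1410 had an unadjusted p under 0.05. No injury gene among those named above passed, with Sox11 at -0.05 (limma adjusted p = 0.97), Atf3 at -0.07 (0.94), Ddit3 at -0.04 (0.96) and Ecel1 at -0.23 (0.89). Sprr1a was higher by 0.48 (limma adjusted p = 0.88), and by 0.29 without Cre-positive uncrushed replicate 4. Pou4f2 differed by 0.28 and Edn2 by 0.70 (limma adjusted p = 0.88 for both). Map3k12 itself did not pass among all genes in this comparison (-0.43, limma adjusted p = 0.88).

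No member of any list passed in uncrushed retinas, yet camera called 8 lists, none of which held. The interferon and complement list was higher (median 0.24, 0 of 26, camera adjusted p = 2.1e-06, and adjusted p = 0.44 with an estimated correlation). So were ganglion cell markers (0.08, 0 of 24, 1 adjusted over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.29 with an estimated correlation) and microglia and macrophage markers (0.13, 0 of 20, 0.0038, and adjusted p = 0.46 with an estimated correlation). Cholesterol synthesis (0.06, 0 of 20, camera adjusted p = 0.0056) and Müller glia markers (0.08, 0 of 15, 0.0057) both had an adjusted p = 0.29 with an estimated correlation. Reactive gliosis (0.08, 0 of 21, 1 adjusted over the list alone, camera adjusted p = 0.0074) and rod markers (0.05, 0 of 17, 0.033) both had an adjusted p = 0.46 with an estimated correlation. Cornea, iris and ciliary body markers had a median of 0.74 (0 of 9, camera adjusted p = 0.0088, and adjusted p = 0.29 with an estimated correlation), with Krt12 at 1.44 (limma adjusted p = 0.89). Esr1 was the 1 gene left without the cornea-rich and lens-rich arrays, with slide as a fixed term or with the uncrushed groups fitted alone.

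The effect of Cre after injury was read from 5 Cre-positive and 3 Cre-negative crushed retinas. Ganglion cell markers were higher and axon injury and stress genes lower in Cre-positive retinas. Pou4f2 was higher by 1.69 (SE 0.14, limma adjusted p = 7.2e-07), Rbpms2 by 1.43 (SE 0.06, limma adjusted p = 2.8e-10) and the sodium channel subunit Scn4b by 1.71 (SE 0.10, limma adjusted p = 4.6e-09). Chac1 was lower at -1.86 (SE 0.13, limma adjusted p = 1e-07), Sox11 at -1.84 (SE 0.11, limma adjusted p = 1.2e-08) and Hrk at -1.58 (SE 0.13, limma adjusted p = 9.3e-07). In limma 299 genes passed, 159 higher and 140 lower in Cre-positive retinas, and 11 and 16 of them at least 2-fold.

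Esr1 was highest of all (3.71), followed after Scn4b by Ctxn3 (1.70), Isl2 (1.39), Irx2 (1.14, with another probe at 0.11), Chrna6 (1.06), Irx4 (1.03) and 1110032F04Rik (1.01). Lower in Cre-positive retinas were also Gm13889 (-1.79), Colec10 (-1.74), Sprr1a (-1.73), Ecel1 (-1.62), Sprr2g (-1.61), Cox6a2 (-1.36) and Tnfrsf12a (-1.29). Ganglion cell markers were higher in 12 of 24 (16 adjusted over the list alone; median 0.41, camera adjusted p = 1.7e-25), including Pou4f1 (0.83), Nefh (0.66), Nefl (0.48), Thy1 (0.39) and Rbpms (0.45, with the lowest of its 3 probes at 0.12). With processed signals Nefl gave -0.01. Its mean Cy5 signal was 14400 in Cre-positive and 8320 in Cre-negative crushed retinas, and its dim Cy3 signal 86.6 and 69.8. The integrated stress response list was lower in 12 of 25 (15 adjusted over the list alone; median -0.36, camera adjusted p = 5.4e-27), including Gdf15 (-0.85), Ddit3 (-0.73), Asns (-0.65) and Phgdh (-0.61). Axon injury genes were lower in 9 of 28 and higher in 1 (10 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 1.8e-12), with Atf3 at -1.17. The AP-1 and JNK list was lower in 3 of 28, Atf3, Fosl2 (-0.53, call lost in 24 of the alternatives run) and Maff (-0.38, lost in 23) (10 lower and 1 higher adjusted over the list alone; median -0.10, camera adjusted p = 0.00036). The list of p53 targets was lower in 2 of 17, Cdkn1a (-0.93, with another probe at -0.01) and Trp53inp1 (-0.25) (3 adjusted over the list alone; median -0.04, camera adjusted p = 0.00099). These calls held with an estimated correlation.

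Further calls in crushed retinas were lost. Apoptosis genes were lower in 2 of 23, Hrk and Ddit3 (4 adjusted over the list alone; median -0.02, camera adjusted p = 0.0034, and adjusted p = 0.11 with an estimated correlation), and Bbc3 gave -0.35 (limma adjusted p = 0.059). Immediate early genes were lower in 1 of 13, Arc at -0.46 (3 adjusted over the list alone; median -0.30, camera adjusted p = 2.8e-05, and adjusted p = 0.069 with an estimated correlation). Fry called apoptosis and immediate early genes (fry adjusted p = 0.01 for both), but not the microglia and macrophage, interferon and complement, or pigment epithelium lists. Microglia and macrophage markers had 0 of 20 past the test and 8 higher adjusted over the list alone (median 0.23, camera adjusted p = 2.2e-05, and adjusted p = 0.24 with an estimated correlation). The interferon and complement list had 0 of 26 and a median of 0.19 (camera adjusted p = 0.00036, and adjusted p = 0.48 with an estimated correlation), and pigment epithelium markers 0 of 12 and a median of 0.50 (camera adjusted p = 0.00067, and adjusted p = 0.24 with an estimated correlation). Among horizontal cell markers, without a call, Calb1 was higher by 0.31 (limma adjusted p = 0.041, lost in 16 of the alternatives run). Gfap differed by 0.22 (limma adjusted p = 0.58). With slide as a fixed term 144 genes passed, of which 37.5% were higher against 53.2% here. Slide 1 held Cre-positive arrays alone and slide 5 Cre-negative ones alone, so slide and Cre were only partly separable in both Cre effects. Processed signals gave 211 genes with 32.7% higher. Placing the array of disagreeing labels as titled gave 118 genes and as described 434, array weights gave 543, and the position pair on the slide (1 and 2, or 3 and 4) as a covariate 475.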

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

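The counts over other splits of the arrays were planned, and the tests of ganglion cell loss, dilution, slide position, the Esr1 probe and the cornea-rich array were chosen only after the result was seen.

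The crush responses differed between the genotypes for 105 genes by the test of the difference itself, and the named genes among those fixed in advance were Pou4f2 (1.40), Pou4f1 (0.91), Sprr1a (-2.21), Sox11 (-1.80), Hrk (-1.47), Ecel1 (-1.39), Atf3 (-1.09) and Ddit3 (-0.69). By camera 7 lists differed, with medians of -0.42 for the integrated stress response, -0.24 for axon injury genes, -0.18 for immediate early genes, -0.10 for apoptosis, -0.10 for AP-1 and JNK, -0.09 for p53 targets and 0.30 for ganglion cell markers, and the calls for immediate early genes and for AP-1 and JNK were lost with an estimated correlation. Relabelling Cre within crushed and within uncrushed arrays gave as many genes in 4 of 100 relabellings, the real one included, with 142 as the highest other. The 3 other relabellings moved 4, 4 and 2 uncrushed arrays and gave 142, 119 and 133 genes. In each of them 0 crushed arrays were relabelled. They therefore kept the real Cre split of the crushed arrays, which called 299 genes in its own contrast, and were not free of a Cre effect. For that reason the share of 4 in 100, from sampled relabellings, cannot decide on chance, and it does not exclude it.

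For the other contrasts the splits moved arrays freely across slides, so they kept no pairing of eyes from the same animal, if there is any. The Cre-negative crush response called 548 genes, and 1 of 35 splits gave as many, the real one, with 1 gene as the highest other. The Cre effect called 299 genes in crushed retinas (1 of 56 splits, highest other 3) and 3 in uncrushed retinas (1 of 100 splits, highest other 1). Esr1 is among the genes called in uncrushed retinas, and a count this near the highest other does not exclude chance for the rest. The Cre-positive crush response called 195 genes, and 2 of 100 splits gave as many. The other split called 1137 genes, several times the real count, which points to a structure of the Cre-positive samples other than crush. It set crushed replicates 1, 3 and 5 and uncrushed replicates 1 and 3 against the other arrays, a division that follows none of slide, sex and slide position exactly. Both Cre-positive arrays of slide 2 fell in the first set and both of slide 4 in the other, while slides 1 and 3 were divided. The cause of this division was not identified.

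Ganglion cell markers fell after crush in Cre-negative retinas, and 3 explanations were tested. Death of ganglion cells at a single rate, with these markers made mainly by ganglion cells, would lower them alike. However, at least 50% of the 24 markers lay over 3 SE from any common change. The common change within 3 SE of the largest number of markers was -0.16. The premise that ganglion cells mainly make these markers was not tested, and the offset shrinks changes of dim markers more. The test therefore does not exclude death at a single rate. Dilution by other ocular tissue would lower the markers of other retinal neurons as well, but the lowest of the rod, bipolar and amacrine medians lay 0.27 above the ganglion cell median of -0.36. An effect of odd against even slide positions alone would act alike in both genotypes, but 5 list members passed the test of the difference. Most Cre-positive arrays lay at positions 1 and 2 and most Cre-negative ones at 3 and 4. An effect of single positions was therefore not excluded. An unequal loss of transcripts in surviving cells, with or without cell death, stays open as a hypothesis, since whole-retina RNA has no count of cells.

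The Esr1 probe lay 2.3 log2 units higher on the lowest Cre-positive than on the highest Cre-negative array. A rise of the full-length endogenous transcript is argued against by the other probe above background, whose change was 2.1% of that of the bright probe in size and negative. A candidate explanation is a transgene transcript that carries part of the estrogen receptor, which the gap of 2.3 fits, but the place of the probe in the receptor was not known. The rise of the probe by 0.72 after crush in Cre-positive retinas has no tested explanation.

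Cre-positive uncrushed replicate 4 was highest in 5 of 5 cornea markers, with Krt12 at 5.54 (highest other array 3.50), Krt5 at 3.10 (1.18), Krt14 at 1.72 (-1.23), Aldh3a1 at 1.33 (-0.88) and Krt15 at 2.02 (-0.54). The array also had the most outlier-marked spots (234, lowest of any array 143), but 0 of them were spots of these markers or of their 109 neighbours. A local fault is argued against by those neighbours, which had a median of -0.05 in log2 Cy5 over the other arrays of the group (SD 0.54), against 4.05 for the marker spots. Cornea carried over in dissection is a candidate explanation, found and tested on the same 5 genes, and no biological explanation was tested.

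A sample lay far from the rest of its group in 8 of 141 groups of values tested, where chance at about 1 in 20 would give 7.05. Sprr1a was -2.02 in Cre-positive uncrushed replicate 4 (others -3.17 to -2.89), Gap43 3.89 in Cre-positive crushed replicate 3 (3.44 to 3.57) and Gfap 0.31 in Cre-negative uncrushed replicate 2 (0.42 to 0.44). Cre-positive crushed replicate 5 lay far in Edn2 at 4.58 (3.8 to 3.89), in its mean lens crystallin score at 0.97 (-0.13 to -0.03) and in its reactive gliosis score at 0.84 (0.18 to 0.30). The cornea, iris and ciliary body score was 0.06 in Cre-negative uncrushed replicate 4 (-0.40 to -0.35), and the interferon and complement score 0.16 in Cre-positive uncrushed replicate 3 (-0.30 to -0.20).

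The array with disagreeing labels, which no comparison used, was set against the 4 Cre-negative uncrushed arrays alone and not against the crushed ones. Of the lists given next, all but lens crystallins were called higher by camera after crush in Cre-negative retinas. The array lay above the range of the uncrushed arrays in 9 mean list scores. These were 0.14 for AP-1 and JNK (range -0.11 to -0.01), 0.18 for apoptosis (-0.13 to -0.10), 0.48 for axon injury genes (-0.29 to -0.19), 0.35 for the integrated stress response (-0.21 to -0.16), 0.19 for interferon and complement (-0.42 to -0.30), 0.68 for lens crystallins (-0.18 to 0.22), 0.29 for microglia and macrophages (-0.28 to -0.21), 0.12 for p53 targets (-0.10 to -0.03) and 0.48 for reactive gliosis (-0.42 to -0.30).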

How the results depend on the processing

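The tests with slide within Cre genotype, position pair, sex and the array pair rich in cornea and lens transcripts left out were chosen after the result was seen. Of 166 called results for named genes 40 stayed called under all alternatives run for them, at most 37. Of 57 without a call 13 gained one under some. Placing the array with disagreeing labels as titled left 0 genes called in the difference, so no result of the difference could be among those 40. For named genes 7545 values were the same, 532 lost their call, 50 gained one and 4 reversed, and for lists 2507 were the same, 69 lost their call, 68 gained one and 1 reversed. The Cre effect on Map3k12 stayed called under every alternative run, and was -0.50 to -0.42 as each array was left out (limma adjusted p from 0.0019 to 0.037). The slope of the Cre-positive on the Cre-negative response stayed between 0.355 and 0.418 as arrays were left out, and the reverse slope between 0.947 and 1.25. Dim signal limits genes near background, and 3 arrays limit the Cre-negative crushed group. Aquantile scaling leaves log ratios unchanged by construction. A fit of only the groups compared could not be had for the difference, nor slide within Cre genotype for the Cre effects. Fewer than 37 alternatives were therefore run for those contrasts. No paired analysis was possible because the labels do not tie an injured eye to its uninjured partner. Crushed and uncrushed retinas of a genotype on a slide matched in sex, so some may be eyes of the same animal, and with slide within Cre genotype as a fixed term, which would absorb a shared animal in part, 418, 201 and 79 genes passed in the Cre-negative and Cre-positive crush responses and the difference. Position parity, which goes with crush, could not be fitted.

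Placing the array with disagreeing labels as its title states gave 72 genes in the Cre-negative crush response in place of 548, 10 in the Cre-positive one in place of 195, 0 in the difference in place of 105 (1972 at an unadjusted p under 0.05 in limma), and 118 for the Cre effect in crushed retinas in place of 299. The reverse slope was then 0.613 and the crush responses shared 1 gene in place of 98. On that array Ecel1 was 4.36, against 4.49 to 4.55 in Cre-negative crushed and 0.93 to 1.15 in Cre-negative uncrushed retinas. Its Pou4f2 was 2.33, against 2.62 to 2.72 and 4.06 to 4.97. The placement as titled thus set the array in a group unlike it in these strongly crush-responsive genes. Placing it as its description states gave 742, 189, 120, 3 and 434 genes in the 5 contrasts. Array weights gave 1198 genes in the Cre-negative crush response, 159 in the difference and 543 for the Cre effect in crushed retinas. Processed signals gave 68 in the difference, slide as a fixed term 144 and the position pair on the slide (1 and 2, or 3 and 4) 475 for the Cre effect in crushed retinas. The Cre-positive crush response had 52 genes with its 2 groups alone and 120 without the cornea-rich and lens-rich arrays. The Cre effect in uncrushed retinas had 1 gene in place of 3 under processed signals, the filter on both channels, slide as a fixed term, its groups alone, the position pair, and without the cornea-rich and lens-rich arrays, and with Cy5 alone 66.7% of its genes were higher. For the other settings the cause was not tested. Of the 49 list calls 26 held with an estimated correlation.

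Leaving out each array gave 325 to 679 genes in the Cre-negative crush response, 112 to 237 in the Cre-positive one, 77 to 120 in the difference, 1 to 3 for the Cre effect in uncrushed and 161 to 324 in crushed retinas, 64 to 115 shared genes and 45 to 54 list calls. The Cre-negative count was 325 without crushed replicate 1 and 331 without crushed replicate 3, and the shared genes were 64 without either. The Cre-positive count was 112 without uncrushed replicate 2, 119 without uncrushed replicate 5 and 129 without crushed replicate 5. The count for the Cre effect in crushed retinas was 189 without Cre-negative crushed replicate 1 and 161 without replicate 2. In uncrushed retinas 1 gene was left without any of the 4 Cre-negative uncrushed arrays, Cre-positive uncrushed replicate 1, 2, 4 or 5, Cre-positive crushed replicate 2, 4 or 5, or Cre-negative crushed replicate 2.

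With processed signals Nefl gave 0.08 in the Cre-negative crush response and -0.01 for the Cre effect in crushed retinas. Its mean Cy5 signal fell from 19800 to 8320 with crush, while its dim Cy3 signal went from 104 to 69.8. Esr1 gave -0.15 in uncrushed and -0.41 in crushed retinas, because another probe, as for 183 genes, had the highest mean intensity, and the probe used here gave 6.72 and 7.23. The lens crystallins in the Cre-positive crush response turned downward without crushed replicate 5 (camera adjusted p = 0.94), and that p ranged from 0.00027 to 0.94 as arrays were left out.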

Other observations

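All tests in this part were chosen after the result was seen. A pair of gene families outside the fixed lists stood out among the genes called after crush in Cre-negative retinas. Of 89 measured potassium and sodium channel subunits, which shape the firing of neurons, 7 were lower and 0 higher, where 0.917 would be expected (two-sided Fisher exact p = 3.7e-05). They were Scn4b (-2.03), Kcnd2 (-1.23), Kcna2 (-0.54), Scn2b (-0.51), Kcnj5 (-0.46), Kcns3 (-0.45) and Kcnc1 (-0.34). In Cre-positive retinas 1 of the 89 was called, and 2 passed the test of the difference. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 8 were higher where 0.349 would be expected (two-sided Fisher exact p = 8.2e-10): Cars (0.62), Gars (0.54), Sars (0.49), Tars (0.48), Nars (0.47), Aars (0.44), Yars (0.32) and Lars (0.24). The family's median was 0.19 in Cre-negative and 0.05 in Cre-positive retinas, where 0 were called, and 1 passed the test of the difference. Both families were picked from the called genes, and Cars, Sars and Aars are in the stress list, so these p-values are not independent evidence, and genes are not independent replicates.

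The array with disagreeing labels had log2 ratios of 4.36 for Ecel1 (Cre-negative crushed 4.49 to 4.55, Cre-negative uncrushed 0.93 to 1.15), 1.81 for Sox11 (1.85 to 1.97, and -1.05 to -0.99), 2.75 for Hrk (2.89 to 2.98, and 0.70 to 0.98), 0.81 for Atf3 (0.71 to 0.85, and -1.29 to -1.17), 2.33 for Pou4f2 (2.62 to 2.72, and 4.06 to 4.97), 1.65 for Gfap (0.84 to 1.35, and 0.31 to 0.44) and 2.34 for Map3k12 (2.32 to 2.61, and 2.21 to 2.58). It also had 0.23 for Ddit3, -0.34 for Sprr1a, 2.49 for Pou4f1, 5.59 for Nefl and 4.22 for Edn2. It lay at position 4 of its slide. Its group was not inferred from these values. Its mean ganglion cell score was -0.49.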
